A study of Homo sapiens with 6 samples.

How the data were processed

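RNA was measured by sequencing in 3 libraries of HepG2-labelled cells expressing a Flag tag and 3 of the same cells expressing Flag-tagged PPFIA1, all labelled Day 1 and untreated. Per the labels' protocols, cells grew in DMEM with 10% serum, RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra RNA kit, which does not mark strand. Groups and replicate numbers were taken from the sample titles and characteristics. Whether replicates were separate cultures, and whether equal numbers in both groups mark a shared day, was not given in the sources used here.

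Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the build was GRCh38 (hg38); the roles of the tools, the strand setting of counting and the annotation release were not given in the sources used here. The deposited table lists 27211 genes with Ensembl identifiers, symbols, types and coordinates. Its signal per library is a read count divided by 1 factor per library, as the deposited values show: in each of the 6 columns 100% of values were whole multiples of 1 step within 0.01 reads, and the factors equalled median-ratio size factors. The deposited group means are the means of these normalised counts. The deposited log2 fold changes of Flag-PPFIA1 over Flag, and the p-value and adjusted p-value columns beside them, came from the authors' own test, DESeq2 1.20.0 being the only testing tool among those named per the submitters' processing notes. In the deposited table the adjusted p of genes with few reads is listed as 1.

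The design assumed edgeR for raw counts and limma for normalised values. Since the deposited columns held normalised counts, the limma branch was used. Genes with a mean over the 6 libraries under 10 normalised counts were left out, which kept 14640. Values were transformed as log2(value + 1), so that fold changes understate the change of genes with few reads, and Flag-PPFIA1 was compared with Flag in a linear model over all 6 libraries without covariates (limma 3.58.1 in R 4.3.3, empirical Bayes with an intensity trend; 4 residual and 10.3 prior degrees of freedom). All p-values are two-sided with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05, and a stricter count also asked for an absolute log2 fold change of at least 1. For single genes a two-sided exact permutation test of group means was added, whose smallest p with 3 against 3 is 0.1. SDs are between the 3 libraries of a group, and SEs are from limma.

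Gene lists were fixed before the data were examined, as were the design, the rule for named genes and the alternatives not marked otherwise. Of 46 lists 41 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, with BH adjustment over the 41 lists and PPFIA1 left out of every list test. By this test 10 lists passed, of which 0 passed with the correlation estimated from the data. For the NF-kB, ATF4, cholesterol and acute phase lists the estimate (-0.03, -0.022, -0.016 and -0.061) lay below the preset value. A higher correlation between members is thus not why these were lost. For the others among the 10 the estimate lay above it, but whether that is why they were lost was not tested. Limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 14, of which 8 are among the 10. Each list's count was also adjusted over the list alone. Named genes are PPFIA1 and the other liprins, the 10 largest rises and 10 largest falls among protein-coding genes past the threshold whose groups do not overlap and whose mean reaches 100 normalised counts in a group, and up to 4 members with the smallest adjusted p from each list that passed or had at least 3 members called. Chance alone keeps 2 groups of 3 from overlapping in 10% of genes. Other-cell-type, mitochondrial, histone and ribosomal lists were to be given as counts, so members named from them, like genes named outside the rule, were chosen after their values were seen.

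Alternatives were a replicate block, each library left out, no filter or a minimum mean of 50, further TMM or upper-quartile scaling, limma without the intensity trend, pseudocounts of 0.1 and 10, an adjusted p under 0.01, protein-coding genes alone, and DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood) on the recovered reads, which called 1510 and 1572 genes. Added after seeing the data were a correction for GC content (a lowess curve with span 0.3 subtracted from each library), a term for Flag-PPFIA1 replicates 2 and 3, which makes the comparison that of Flag-PPFIA1 replicate 1 with Flag (3 residual degrees of freedom, the lone library assumed to vary like the others), and both together. GC content came from GENCODE release 29, in which 27207 of the 27211 genes (99.99%) had identical coordinates, and was known for 27195 (99.94%). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 read the table and drew the plots.

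The limma, edgeR and DESeq2 code was tested on simulated counts for 14637 genes with the means and depths of these libraries, of which 200 were changed. For the simulated comparison of Flag-PPFIA1 with Flag, limma recovered 80% of genes changed 1.5-fold and 99% of those changed 2-fold, edgeR 83% and 99%, and DESeq2 76% and 97%. Limma also called 11 unchanged genes, and camera called a raised list (adjusted p = 3.06e-45) and 0 of 40 null lists. The simulated genes varied independently, without the GC trend or the library differences of the real data. The simulated rates of false calls therefore do not carry over to the real libraries. Depth ranged from 10551353 to 14555507 reads in genes, so a gene with a mean near 10 normalised counts rests on about as many reads per library. The identity of the cell line was not tested. Values of a few named genes and of 1 list are not reported here.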

Results

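Total RNA was extracted with TRIzol and sequenced in 6 libraries, prepared with a NEBNext Ultra RNA kit, from cells labelled HepG2, a human liver cancer line, on Day 1 of the experiment. In 3 libraries the cells expressed a Flag tag alone, and in 3 they expressed Flag-tagged PPFIA1. PPFIA1 encodes liprin-alpha-1, a scaffold protein found at focal adhesions and at sites where microtubules attach to the cell cortex. The comparison asks which transcripts differ when PPFIA1 is overexpressed. Flag replicates 1, 2 and 3 held 13851894, 10551353 and 12844006 reads in genes, and Flag-PPFIA1 replicates 1, 2 and 3 held 14555507, 12031811 and 11142616. The labels do not say that replicates were separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. Camera p-values at the preset correlation weigh the genes of a list against other genes. They do not measure the spread between libraries, and very small ones rest on many genes, not on many libraries.

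PPFIA1 was 1.93 times as abundant in the Flag-PPFIA1 libraries, at 2369 ± 183 normalised read counts against 1229 ± 57.1 in Flag (mean ± SD, n = 3 each). The gene (ENSG00000131626) lies on chromosome 11 from 70270700 to 70385312 in GRCh38. Flag replicates 1, 2 and 3 held 1266, 1258 and 1163 normalised counts, and Flag-PPFIA1 replicates 1, 2 and 3 held 2159, 2489 and 2459. The log2 fold change was 0.94 (SE 0.072, limma, BH adjusted p = 1.78e-05), while the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. Without limma's intensity trend the BH adjusted p was 0.0933. Fold changes are on the log2(normalised count + 1) scale, which understates the change of genes with few reads. Reads from the construct and from the cells' own gene cannot be separated in gene counts, and 5.9% of PPFIA1 exon bases also lie in another gene, mainly AP000487.1 on the opposite strand.

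Among the other liprins, PPFIBP1, which encodes liprin-beta-1, a partner of the liprin-alpha proteins, rose from 1239 ± 72.2 to 1560 ± 59.7 normalised counts (SD, n = 3), a log2 change of 0.33 (SE 0.069, limma, BH adjusted p = 0.0134), and stood at 0.29 for replicate 1 of Flag-PPFIA1 alone (limma, BH adjusted p = 0.0719). PPFIA4 stood at 156.0 ± 35.2 and 199.2 ± 58.5 (log2 0.33, limma, BH adjusted p = 0.305). PPFIA3 stood at 144.4 ± 11.9 and 118.8 ± 2.67 (log2 -0.28, limma, BH adjusted p = 0.181). PPFIBP2, at a mean of 8.66 normalised counts, lay under the minimum for testing, and PPFIA2 was absent from the deposited table. Of the 3 liprins tested besides PPFIA1, 1 rose, also when adjusted over the list alone. None of the 8 tested neighbours of PPFIA1 in 11q13, a segment often amplified in cancer that holds CCND1 and CTTN, was called by limma over all genes or adjusted over the list alone (0 of 8; 1 lower at an unadjusted p under 0.05; 0 by DESeq2 and edgeR). Their median log2 change was -0.07 (camera adjusted p = 0.609). GC-corrected, 1 of the 8 was called higher, DHCR7 at 0.26 (limma, BH adjusted p = 0.0340; 0.13 and not past the threshold uncorrected), and the list median was -0.01 with the test direction up (camera adjusted p = 0.705). With replicate 1 alone 0 of the 8 passed by limma (0 also at an unadjusted p under 0.05).

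**Figure D1:**
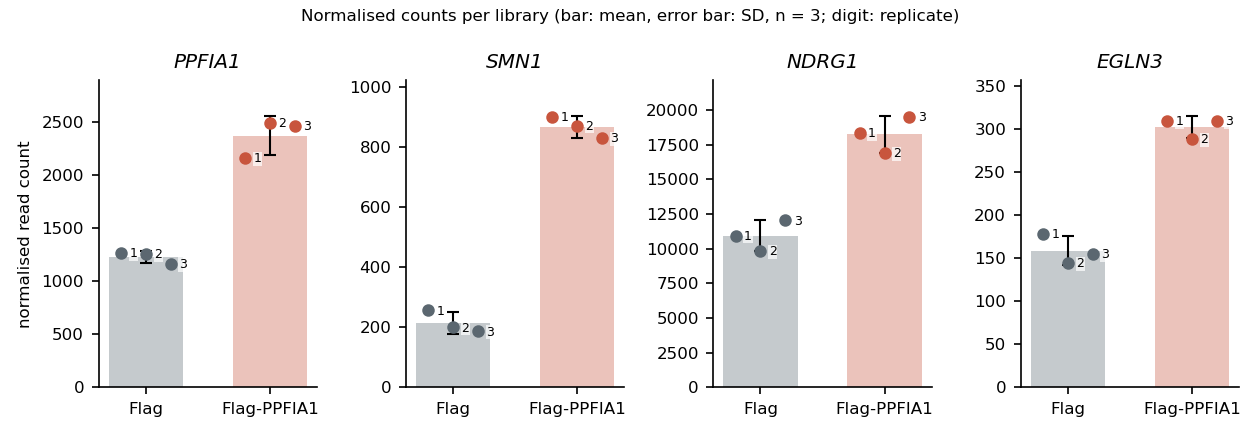
Normalised read counts (y axis) of PPFIA1, SMN1, NDRG1 and EGLN3 in each library, with Flag and Flag-PPFIA1 libraries as points numbered by replicate and bars for the mean and SD (n = 3 per group). PPFIA1 lies between 1163 and 1266 in the Flag libraries and between 2159 and 2489 in the Flag-PPFIA1 libraries.

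Flag-PPFIA1 replicates 2 and 3 stood apart from the other 4 libraries on the first principal component, and Flag-PPFIA1 replicate 1 stood apart on the second. On the first, which held 65.5% of the variance over 10212 genes, the Flag libraries scored -0.31, -0.44 and -0.30, Flag-PPFIA1 replicate 1 scored -0.05, and replicates 2 and 3 scored 0.59 and 0.52. On the second, which held 11.2%, Flag-PPFIA1 replicate 1 scored 0.87 and the other libraries from -0.43 to -0.03. Mitochondrial tRNA took 0.0328%, 0.0328% and 0.0329% of reads in the Flag libraries and 0.0354%, 0.0202% and 0.0142% in Flag-PPFIA1 replicates 1, 2 and 3. Genes of low GC content read higher in both libraries, with a median log2 difference from Flag of 0.33 and 0.23 in the lowest GC decile (median GC 36.8%) and of -0.31 and -0.22 in the highest (63.8%). For Flag-PPFIA1 replicate 1 the corresponding medians were 0.12 and -0.08. Longer genes read higher too: the Spearman correlation of gene length with the difference from the other Flag libraries was 0.231, 0.185 and 0.232 in Flag-PPFIA1 replicates 1, 2 and 3. In the Flag libraries it was 0.064, -0.156 and 0.109. Genes shorter than 1000 bases took 3.34%, 3.07% and 2.93% of reads in Flag-PPFIA1 and 3.22%, 3.33% and 3.15% in Flag. No fit corrected for length. Chi-square per degree of freedom was 17.1 and 15.8 between Flag-PPFIA1 replicate 1 and replicates 2 and 3, 4.06 between replicates 2 and 3, and 2.47 to 3.16 among the Flag libraries, so no pair differed by so little as to be one library deposited again. A pair of further fits was chosen after seeing this. One gives replicates 2 and 3 a term of their own, which leaves Flag-PPFIA1 replicate 1 alone against Flag ("replicate 1 alone"), and the other subtracts a smooth curve on GC content from each library ("GC-corrected").

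**Figure D2:**
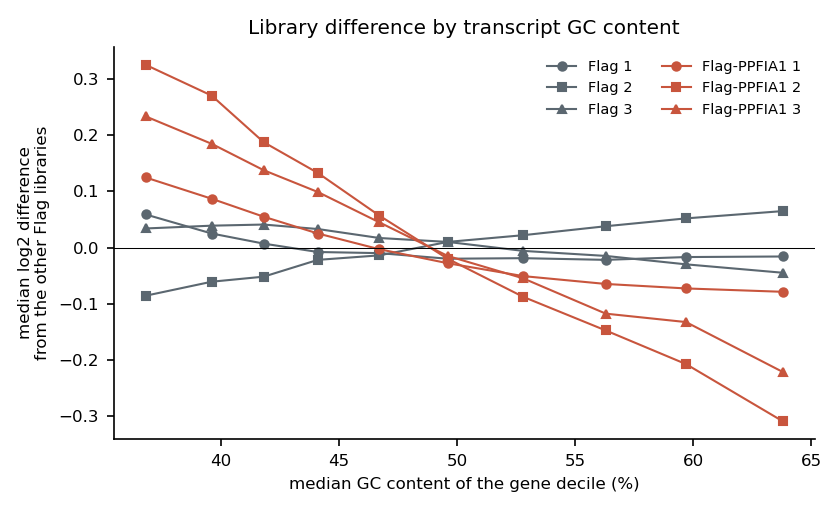
Median log2 difference from the other Flag libraries (y axis) for genes in each decile of GC content (x axis, percent), one line per library. Flag-PPFIA1 replicates 2 and 3 fall from 0.33 and 0.23 in the lowest decile to -0.31 and -0.22 in the highest.

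Across the transcriptome, 1683 of 14640 tested genes changed, 902 higher and 781 lower in Flag-PPFIA1 cells (limma, BH adjusted p under 0.05). DESeq2 called 1510 (874 higher, 636 lower), the same genes as in the authors' deposited table, and edgeR 1572 (916 and 656). Limma without the intensity trend called 0, with 3483 at an unadjusted p under 0.05. Changes were mostly small, as 53 genes changed at least 2-fold. The balance at 2-fold depended on the method, with 22 higher and 31 lower by limma, 8 and 2 by DESeq2, 24 and 23 by edgeR, and 19 and 13 GC-corrected. Among protein-coding genes whose groups did not overlap and whose mean reached 100 normalised counts in a group, SMN1 rose most on the log2 scale, followed by CXCL8, STC1, PPFIA1, ANTXR2, EGLN3, CLEC2B, ANGPTL4, SPOCK1 and BIRC3. By type, 872 of 12322 protein-coding genes rose and 727 fell, against 8 and 12 of 543 lincRNA genes, 2 and 13 of 655 antisense genes and 17 and 14 of 367 processed pseudogenes. Reads of the last 2 types are uncertain. Pseudogenes share sequence with their parent genes, and the library kit does not mark strand, so antisense reads cannot be told from those of an overlapping gene. The count was 192, 64 and 235 without Flag replicates 1, 2 and 3 (148, 60 and 164 higher; 44, 4 and 71 lower). It was 4809, 282 and 154 without Flag-PPFIA1 replicates 1, 2 and 3 (2521, 193 and 123 higher; 2288, 89 and 31 lower). The share of higher genes thus ran from 52.4% to 93.8%, against 53.6% with all libraries. At 2-fold the corresponding counts were 17, 5, 18, 243, 12 and 11, of which 12, 4, 11, 74, 7 and 6 were higher. For replicate 1 alone, 209 genes changed (162 higher, 47 lower; 184 shared with the 1683 in direction), and GC-corrected values gave 733 (417 higher, 316 lower; 537 shared).

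SMN1, which encodes the survival motor neuron protein of the spliceosomal assembly machinery, rose from 213.7 ± 36.9 to 865.4 ± 35.5 normalised counts (SD, n = 3), a ratio of 4.05. SMN1 (ENSG00000172062) lies on chromosome 5 from 70925030 to 70953942 in GRCh38, and its log2 change was 2.03 (SE 0.111, limma, BH adjusted p = 3.95e-07), 2.08 for replicate 1 alone and 1.91 GC-corrected. Its near-identical copy SMN2 stood at 163.9 ± 6.2 and 201.8 ± 10.6, so how reads were split between both copies is uncertain. CXCL8, which encodes the neutrophil-attracting chemokine interleukin-8, rose from 55.3 ± 11.7 to 151.7 ± 10.5 (log2 1.46, SE 0.180, limma, BH adjusted p = 7.94e-04). BIRC3, an inhibitor of apoptosis in TNF receptor signalling, rose by log2 0.88 (SE 0.093) and STC1, a secreted glycoprotein, by 0.99 (SE 0.174). EGLN3, an oxygen-sensing prolyl hydroxylase, rose by 0.93 (SE 0.115), and ANGPTL4, an inhibitor of lipoprotein lipase, by 0.91 (SE 0.155). The anthrax toxin receptor gene ANTXR2 rose by 0.93 (SE 0.204), CLEC2B, a C-type lectin, by 0.92 (SE 0.152), and SPOCK1, a proteoglycan, by 0.89 (SE 0.172). For replicate 1 alone the values were 1.34 for CXCL8, 0.65 for BIRC3, 0.96 for STC1, 0.96 for EGLN3, 1.198 for ANGPTL4, 0.72 for ANTXR2, 0.72 for CLEC2B and 0.73 for SPOCK1, the last 3 not past the threshold (limma, BH adjusted p = 0.224, 0.0603 and 0.137).

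The 10 largest falls were in C4orf48, TAF10, CHCHD10, METRN, PRAF2, VIT, ATOX1, RPS28, VSIR and MT1E, with log2 changes from -1.31 to -0.89. TAF10 encodes a subunit of the general transcription factor TFIID, CHCHD10 a mitochondrial protein of the intermembrane space, ATOX1 a copper chaperone, RPS28 a ribosomal protein and MT1E a metallothionein. C4orf48 fell from 275.1 ± 12 to 123.6 ± 73.8 normalised counts and CHCHD10 from 1135 ± 47.0 to 606.0 ± 378.0 (SD, n = 3). With replicate 1 alone 8 of the 10 did not pass, among them C4orf48 at log2 -0.40, TAF10 at -0.22 and CHCHD10 at -0.12 (limma, BH adjusted p = 0.335, 0.632 and 0.633), and GC-corrected CHCHD10 did not pass (-0.79). METRN, a secreted neurotrophic factor, and VIT, an extracellular matrix protein, fell by 1.03 and 1.00 (SE 0.165 and 0.170), and passed for replicate 1 alone at -0.50 and -1.03 (limma, BH adjusted p = 0.0094 and 0.0224). Exons shared with other genes make several of the 10 uncertain, as 43.6% of PRAF2 exon bases lie in WDR45, 38.9% of TAF10 in ILK, 21.4% of RPS28 mainly in KANK3 and 18.1% of CHCHD10 mainly in MMP11, and MT1E shares sequence with other metallothionein genes. Of the 116 named genes that changed besides PPFIA1, 24 were called in each fit that left out 1 library, all 24 higher. They include SMN1, CXCL8, BIRC3 and EGLN3 and no gene that fell.

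**Figure D3:**
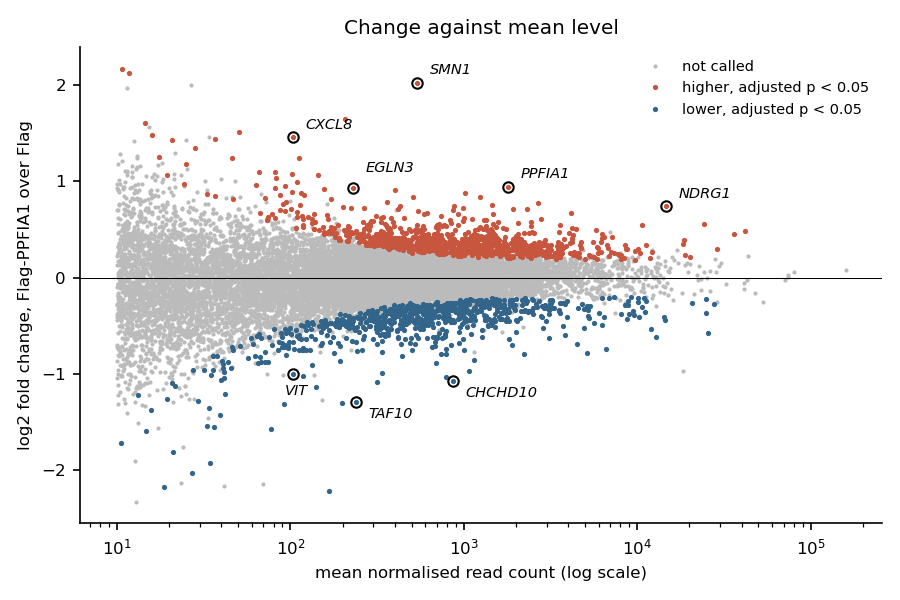
Log2 fold change of each tested gene (y axis) against its mean normalised count (x axis, log scale), with genes that rose or fell (limma, BH adjusted p under 0.05) in colour. Of 14640 genes, 902 rose and 781 fell, and SMN1 has a log2 change of 2.03.

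Genes of the hypoxia response rose together: 23 of 25 tested members rose and 0 fell (0 also at an unadjusted p under 0.05 and by DESeq2 and edgeR), and all 25 had positive log2 changes, with a median of 0.49 (SD 0.220 over members). NDRG1, a stress-response gene, went from 10940 ± 1100 to 18240 ± 1300 normalised counts (SD, n = 3; log2 0.74), ADM, the vasodilator peptide adrenomedullin, from 659.5 ± 27.7 to 1075 ± 39.3 (log2 0.70), LOX, a collagen cross-linking enzyme, from 752.5 ± 56.1 to 1237 ± 52.7 (log2 0.72), and ERO1A, an oxidase of the endoplasmic reticulum, from 1149 ± 40.4 to 1816 ± 95.3 (log2 0.66). All of these have a limma, BH adjusted p of 2.26e-04 and were called without each library in turn. The list median differed from Flag by 0.43, 0.45 and 0.51 in Flag-PPFIA1 replicates 1, 2 and 3. Adjusted over the list alone 24 rose and 0 fell. By limma's camera test the list passed (adjusted p = 3.68e-16; adjusted p = 0.210 with an estimated correlation). Replicate 1 alone gave a median of 0.43 with 17 higher, and GC-corrected values 0.44 with 19 higher (camera adjusted p = 6.57e-18 and 2.87e-19).

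Glycolytic genes rose in part: 7 of 20 tested rose and 1 fell (10 and 0 by DESeq2, 8 and 0 by edgeR), or 10 and 1 adjusted over the list alone, with a median log2 change of 0.19. The 1 lower gene, the aldolase gene ALDOA at -1.14, stood at -0.07 for replicate 1 alone and at -1.05 GC-corrected, neither past the threshold (limma, BH adjusted p = 0.922 and 0.0623). HK2, a hexokinase, rose from 1268 ± 41.4 to 1901 ± 157.0 normalised counts (SD, n = 3; log2 0.58, SE 0.072), the glucose transporter gene SLC2A1 by log2 0.34 (SE 0.060), the enolase gene ENO2 by 0.40 (SE 0.076) and the lactate dehydrogenase gene LDHA by 0.30 (SE 0.066). The list shares 4 tested genes with the hypoxia list, 3 of which rose; of the 16 others 4 rose and 1 fell, with a median of 0.15. As a whole the list passed by camera (adjusted p = 0.00282; adjusted p = 0.392 with an estimated correlation). The median was 0.09 for replicate 1 alone, with 4 higher and not ENO2 (0.29) or LDHA (0.21), and 0.21 GC-corrected, with 9 higher (camera adjusted p = 0.00212 and 6.72e-07).

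Targets of NF-kB and TNF signalling rose: 11 of 29 tested rose and 0 fell (2 lower at an unadjusted p under 0.05; 0 by DESeq2 and edgeR), or 15 and 1 adjusted over the list alone, with a median log2 change of 0.25. Besides CXCL8 and BIRC3, SOD2, the mitochondrial superoxide dismutase gene, rose from 1751 ± 72.5 to 2878 ± 246.0 normalised counts (SD, n = 3; log2 0.71, SE 0.071), and IL32, a proinflammatory cytokine gene, from 1946 ± 116.0 to 2904 ± 297.0 (log2 0.57, SE 0.079). The list passed by camera (adjusted p = 3.35e-04; adjusted p = 0.204 with an estimated correlation). With replicate 1 alone the median was 0.30 with 9 higher, and GC-corrected it was 0.34 with 12 higher (camera adjusted p = 3.01e-08 and 6.68e-09).

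Immediate early genes rose as well, 12 of 30 tested against 1 that fell, or 13 and 1 adjusted over the list alone (median log2 change 0.23). JUN, a subunit of the transcription factor AP-1, rose from 792.1 ± 8.37 to 1218 ± 23.9 normalised counts (SD, n = 3; log2 0.62, SE 0.066), and the MAP kinase phosphatase genes DUSP4 and DUSP5 by log2 0.46 (SE 0.077) and 0.56 (SE 0.112). KLF6, a zinc-finger transcription factor gene, rose by 0.37 (SE 0.084). BTG2, an antiproliferative gene, fell by 0.36 on the log2 scale (SE 0.102). Camera called the list (adjusted p = 4.87e-04; adjusted p = 0.356 with an estimated correlation), which shares IER3 with the NF-kB list and ATF3 with the ATF4 list. In replicate 1 alone the median was 0.31 with 6 higher, and GC-corrected it was 0.29 with 11 higher (camera adjusted p = 4.80e-08 and 1.82e-08). DUSP5, KLF6 and BTG2 did not pass for replicate 1 alone (0.49, 0.31 and -0.27), nor BTG2 GC-corrected (-0.33).

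In the acute phase list 2 of 11 tested genes rose and 0 fell (0 also at an unadjusted p under 0.05 and by DESeq2 and edgeR), with the same counts adjusted over the list alone. IL6ST, the signalling receptor subunit for interleukin-6, rose by log2 0.46 (SE 0.068), and the complement gene C3 rose from 3606 ± 58.4 to 4764 ± 324.0 normalised counts (SD, n = 3; log2 0.40, SE 0.063). STAT3, the transcription factor downstream of IL6ST, stood at log2 0.15 and CP, which encodes ceruloplasmin, at 0.54 (limma, BH adjusted p = 0.105 and 0.112). The median was 0.25 (camera adjusted p = 0.0369; adjusted p = 0.355 with an estimated correlation). The list did not pass without Flag replicate 1, Flag replicate 3 or Flag-PPFIA1 replicate 1 (medians 0.158, 0.152 and 0.094; camera adjusted p = 0.0784, 0.103 and 0.256). Nor did it with no filter on low values or a minimum mean of 50 (medians 0.252 and 0.141; camera adjusted p = 0.104 and 0.218). Its median was 0.38 for replicate 1 alone and 0.29 GC-corrected (camera adjusted p = 0.0018 and 0.00765).

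Genes of the unfolded protein response, which raises folding capacity in the endoplasmic reticulum, rose: 13 of 23 tested rose and 1 fell (14 and 1 by DESeq2, 14 and 0 by edgeR), or 14 and 1 adjusted over the list alone, with a median log2 change of 0.27. The chaperone genes HSP90B1 and HSPA5 rose from 19450 ± 323.0 to 28900 ± 4360 and from 34580 ± 293.0 to 48530 ± 5580 normalised counts (SD, n = 3; log2 0.56 and 0.48), DNAJB11, a co-chaperone, by log2 0.59 (SE 0.115), and SEL1L, of the degradation machinery, by 0.34 (SE 0.063). By camera the list passed (adjusted p = 1.27e-04; adjusted p = 0.355 with an estimated correlation). The rise was smaller for replicate 1 alone, with a median of 0.17 and 2 members higher; HSPA5 stood at 0.29 and DNAJB11 at 0.24, the latter not past the threshold (limma, BH adjusted p = 0.146). GC-corrected the median was 0.26 with 12 higher (camera adjusted p = 1.28e-06 for replicate 1 alone and 3.78e-06 GC-corrected). SEL1L did not pass in either (0.26 and 0.17).

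The ATF4 integrated stress response list, of amino acid supply and stress genes, had 11 of 34 tested members higher and 0 lower (1 lower at an unadjusted p under 0.05; 0 by DESeq2 and edgeR), or 13 and 1 adjusted over the list alone (median log2 change 0.12). STC2, a secreted glycoprotein, rose from 878.1 ± 58.3 to 1341 ± 27.8 normalised counts (SD, n = 3; log2 0.61, SE 0.071), GDF15, a stress-induced cytokine, by log2 0.62 (SE 0.089), the cystine transporter gene SLC7A11 by 0.52 (SE 0.068) and DDIT4, an inhibitor of mTORC1 that is also in the hypoxia list, by 0.51 (SE 0.068). Outside the hypoxia list 10 of 33 rose. Camera called the list (adjusted p = 5.24e-04; adjusted p = 0.204 with an estimated correlation), which shares CEBPB with the NF-kB list. The median was 0.18 for replicate 1 alone, with 5 higher, and 0.14 GC-corrected, with 10 higher (camera adjusted p = 7.44e-07 and 3.44e-07).

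Cholesterol synthesis and uptake genes rose in 8 of 27 tested cases and fell in 0 (1 lower at an unadjusted p under 0.05; 0 by DESeq2 and edgeR), or 11 and 1 adjusted over the list alone, with a median log2 change of 0.13. HMGCS1, the HMG-CoA synthase gene of the mevalonate pathway, rose from 1993 ± 73.1 to 2746 ± 159.0 normalised counts (SD, n = 3; log2 0.46, SE 0.065), IDI1, an isomerase of that pathway, by log2 0.53 (SE 0.093), MSMO1, a sterol oxidase gene, by 0.45 (SE 0.081), and the sterol carrier gene STARD4 by 0.49 (SE 0.095). The list passed by camera (adjusted p = 0.00329; adjusted p = 0.210 with an estimated correlation). Replicate 1 alone gave a median of 0.10 with 4 higher, and GC-corrected values 0.15 with 7 higher (camera adjusted p = 6.63e-04 and 3.66e-06). IDI1 did not pass for replicate 1 alone (0.34), nor STARD4 GC-corrected (0.23).

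Cytosolic ribosomal protein mRNAs fell, 13 of 41 tested by limma, 8 by DESeq2 and 5 by edgeR, against 0 that rose by each tool or at an unadjusted p under 0.05, or 16 and 0 adjusted over the list alone, with a median log2 change of -0.10. RPS2 fell from 30390 ± 1120 to 20930 ± 5680 normalised counts (SD, n = 3; log2 -0.57, SE 0.130), RPL13 from 16140 ± 374.0 to 12220 ± 1710 (log2 -0.41, SE 0.082) and RPL18 by 0.27 on the log2 scale (SE 0.063), besides RPS28. As a whole the list passed by camera (adjusted p = 0.00699; adjusted p = 0.571 with an estimated correlation), but not by fry (adjusted p = 0.0839) or without Flag replicate 2 (camera adjusted p = 0.0532). With replicate 1 alone the median was -0.08 and no member passed by limma (0 of 41; 12 lower at an unadjusted p under 0.05, a fit not run with other tools), and GC-corrected it was -0.08 with 9 lower, not RPL18 (camera adjusted p = 0.00166 and 0.00356). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain.

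Nuclear genes of oxidative phosphorylation fell in 11 of 31 tested cases (11 by DESeq2, 8 by edgeR) and rose in 0 (1 higher at an unadjusted p under 0.05; 0 by DESeq2 and edgeR), or 12 and 0 adjusted over the list alone (median log2 change -0.16). NDUFB10 and NDUFA4, of the respiratory chain, fell from 1228 ± 30.5 to 867.1 ± 133.0 and from 2386 ± 25 to 1883 ± 237.0 normalised counts (SD, n = 3; log2 -0.51 and -0.35). COX5B, of cytochrome c oxidase, fell by 0.45 (SE 0.101) and SDHC, of succinate dehydrogenase, by 0.30 (SE 0.072) on the log2 scale. The list passed by camera (adjusted p = 0.00236; adjusted p = 0.463 with an estimated correlation) and not by fry (adjusted p = 0.0521). In replicate 1 alone the median was -0.08 and no member passed by limma (0 of 31; 9 lower at an unadjusted p under 0.05), and GC-corrected it was -0.15 with 9 lower (camera adjusted p = 0.00722 and 7.74e-05).

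Among the 13 mRNAs of the mitochondrial genome 2 rose and 1 fell (1 and 1 by DESeq2 and by edgeR), or 2 and 2 adjusted over the list alone. Their median log2 change was 0.06, their mean -0.04 and the test direction up (camera adjusted p = 0.761). MT-ATP6 and MT-ND6 rose by log2 0.45 (SE 0.090) and 0.55 (SE 0.152), MT-ND5 fell by 0.27 (SE 0.065), and MT-ND4L, whose Flag-PPFIA1 libraries held 13800 ± 9930 normalised counts, stood at -0.97 (limma, BH adjusted p = 0.0548). For replicate 1 alone no member passed by limma, MT-ND6 stood at 0.03 and MT-ND4L at 0.13, and the list median was 0.14. In that fit, which rests on 1 Flag-PPFIA1 library, the list passed by camera at the preset correlation. The correlation between members estimated from the data was 0.261, above the preset 0.01. GC-corrected the median was -0.02 with 1 higher and 1 lower, and MT-ND6 did not pass (0.45). Of 8 tested replication-dependent histone genes 0 rose by limma (0 also at an unadjusted p under 0.05 and by DESeq2 and edgeR) and 1 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.191). Of 6 metallothionein and zinc genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.756). The zinc exporter gene SLC30A1 rose by 0.27 (SE 0.072), MT1E and MT2A fell by 0.89 (SE 0.178) and 0.70 (SE 0.205), and SLC39A10, a zinc importer gene, stood at 0.25 (limma, BH adjusted p = 0.0542). By DESeq2 and edgeR 0 members of the list fell (2 lower by limma at an unadjusted p under 0.05). In replicate 1 alone none passed by limma (0 of 6; 1 higher and 1 lower at an unadjusted p under 0.05), with MT1E at -0.31 and MT2A at 0.03, and GC-corrected MT2A (-0.62) and SLC30A1 (0.07) did not pass. MT1E and MT2A share sequence with other metallothionein genes and are uncertain.

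**Figure D4:**
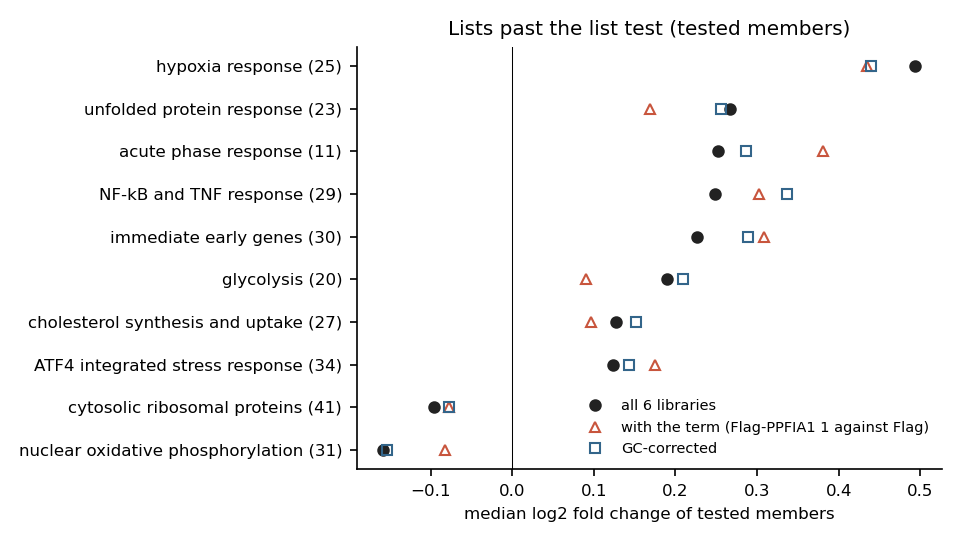
Median log2 fold change of tested members (x axis) for each list that passed the camera test (y axis, number of tested members in parentheses), over all 6 libraries (circles), for replicate 1 alone (triangles) and GC-corrected (squares). Over all libraries the hypoxia list has the highest median, 0.49, and the nuclear oxidative phosphorylation list the lowest, -0.16.

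Adhesion genes, the setting in which liprin-alpha-1 is known, moved in part. Of 36 integrin and focal adhesion genes 7 rose and 1 fell, also when adjusted over the list alone, and the list as a whole did not pass (median log2 change 0.01, camera adjusted p = 0.266). The integrin subunit genes ITGA2, ITGAV, ITGA6 and ITGB8 rose, ITGAV from 1980 ± 105.0 to 2879 ± 204.0 normalised counts and ITGA2 from 720.7 ± 85.7 to 1131 ± 22.5 (SD, n = 3; log2 0.54 and 0.66), ITGA6 by log2 0.44 (SE 0.072) and ITGB8 by 0.73 (SE 0.122). The list median was 0.08 for replicate 1 alone, where ITGB8 did not pass (0.60). In that fit, which rests on 1 Flag-PPFIA1 library, the list passed by camera at the preset correlation. GC-corrected the list also passed at the preset correlation (median 0.07, 8 higher, 1 lower, camera adjusted p = 0.00356). An estimated correlation was used only on uncorrected values over all libraries, and with it the list did not pass (camera adjusted p = 0.463). In the list of cortical microtubule and liprin partners 4 of 29 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.3). PHLDB2, a microtubule-anchoring protein gene, and CAMSAP2, of microtubule minus ends, rose by 0.32 (SE 0.071) and 0.27 (SE 0.070), and the receptor phosphatase gene PTPRS fell by 0.28 (SE 0.078). These 3 stood at 0.19, 0.14 and -0.17 for replicate 1 alone, where 0 of the 29 passed by limma (3 higher and 1 lower at an unadjusted p under 0.05). GC-corrected CAMSAP2 and PTPRS did not pass, at 0.08 and -0.09 (limma, BH adjusted p = 0.394 and 0.409).

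Of 28 extracellular matrix genes 1 rose and 4 fell (2 and 3 by DESeq2, 2 and 2 by edgeR), or 2 and 4 adjusted over the list alone. LOX rose, and LAMB2 and LAMA5, which encode laminin chains, fell by 0.51 (SE 0.101) and 0.38 (SE 0.101) and the perlecan gene HSPG2 by 0.36 (SE 0.080) on the log2 scale. The list median was 0.01, its mean -0.03 and its test direction down (camera adjusted p = 0.939). LAMB2, LAMA5 and HSPG2 did not pass for replicate 1 alone (-0.33, -0.09 and -0.18), nor LAMA5 and HSPG2 GC-corrected (-0.13 and -0.15). In the epithelial-mesenchymal list 2 of 20 rose and 3 fell (1 and 3 by DESeq2, 2 and 3 by edgeR), or 2 and 4 adjusted over the list alone (median 0.01, camera adjusted p = 0.756). The keratin genes KRT8 and KRT18 fell by 0.27 (SE 0.059) and 0.28 (SE 0.064), S100A4, a calcium-binding protein gene, fell by 0.41 (SE 0.080), and ZEB1, a repressor of epithelial genes, rose by 0.37 (SE 0.089). GC-corrected KRT8, KRT18 and ZEB1 did not pass, at -0.16, -0.18 and 0.19 (limma, BH adjusted p = 0.107, 0.0769 and 0.244). KRT18, S100A4 and ZEB1 did not pass for replicate 1 alone (-0.18, -0.19 and 0.40).

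TGF-beta and BMP targets did not pass as a list (5 of 21 rose and 1 fell, 6 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.249). The receptor gene TGFBR1 rose by log2 0.47 (SE 0.063), and ID3, a helix-loop-helix inhibitor gene, fell by 0.62 (SE 0.1). INHBA, an activin subunit gene at 3.46 ± 2.08 and 17.96 ± 3.01 normalised counts, rose by 2.17 (SE 0.479), a value at few reads that no limma fit leaving out 1 library called (0 of 3 in which it was tested). The TGF-beta and BMP list had a median of 0.17 for replicate 1 alone. In that fit, which rests on 1 Flag-PPFIA1 library, the list passed by camera at the preset correlation. GC-corrected it also passed at the preset correlation (camera adjusted p = 0.0322). With an estimated correlation, used only on uncorrected values over all libraries, it did not pass (camera adjusted p = 0.58). Of 24 YAP/TAZ targets 2 rose and 3 fell (1 and 3 by DESeq2), or 4 and 5 adjusted over the list alone (median -0.06, camera adjusted p = 0.609), with NT5E, an ectonucleotidase gene, higher by 0.51 (SE 0.098) and AMOTL1, a YAP-binding protein gene, lower at -0.35 (SE 0.082). The median was 0.05 for replicate 1 alone.

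Cell cycle genes went both ways. Of 34 G2/M genes 8 rose and 1 fell, or 10 and 3 adjusted over the list alone (median 0.09, camera adjusted p = 0.249), ANLN, ECT2 and DLGAP5, of cytokinesis and the spindle, rising by log2 0.31 (SE 0.065), 0.32 (SE 0.065) and 0.40 (SE 0.1) while UBE2C, a ubiquitin-conjugating enzyme gene of mitotic exit, fell by 0.43 (SE 0.086). In replicate 1 alone and GC-corrected, 0 of the 34 rose by limma (4 and 7 higher at an unadjusted p under 0.05; medians 0.01 and 0.03). Of 35 G1/S genes 2 rose and 5 fell (2 and 3 by edgeR), also when adjusted over the list alone (median -0.02, camera adjusted p = 0.609), with CLSPN, a replication checkpoint gene, higher by 0.36 (SE 0.087) and CDT1, a replication licensing gene, lower at -0.46 (SE 0.118). Neither passed for replicate 1 alone (0.19 and -0.13), nor CDT1 GC-corrected (-0.23). Of 26 p53 targets 3 rose and 1 fell, also when adjusted over the list alone (median 0.01, camera adjusted p = 0.609). The cell cycle inhibitor gene CDKN1A rose by 0.37 (SE 0.063; 0.47 for replicate 1 alone), and MDM2, which encodes the ligase for p53, by 0.34 (SE 0.076; 0.25 for replicate 1 alone and 0.22 GC-corrected, neither past the threshold).

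Of 34 interferon response genes 1 rose and 3 fell (1 and 4 by DESeq2, 1 and 2 by edgeR), or 4 and 4 adjusted over the list alone (median 0.02, camera adjusted p = 0.712). IFI6, ISG15 and IFITM2 fell by 0.67 (SE 0.126), 0.46 (SE 0.114) and 0.49 (SE 0.094), and SAMD9 rose by 0.35 (SE 0.074). With replicate 1 alone none of the 34 passed by limma (0 of 34; 3 higher and 4 lower at an unadjusted p under 0.05) and ISG15 stood at -0.12. GC-corrected SAMD9 and ISG15 did not pass, at 0.12 and -0.26 (limma, BH adjusted p = 0.287 and 0.0868), and 0 of the 34 rose (2 higher at an unadjusted p under 0.05). IFITM2 shares 22.7% of its exon bases with IFITM1 and is uncertain. Of 20 heat shock genes 2 rose and 2 fell, or 3 and 2 adjusted over the list alone. The median was -0.002, the mean 0.03 and the test direction up (camera adjusted p = 0.756). HSPH1 and CHORDC1 rose by 0.26 (SE 0.073) and 0.29 (SE 0.087), and HSPB1 and HSPA1B fell by 0.21 (SE 0.063) and 0.43 (SE 0.077). Of these only HSPA1B passed for replicate 1 alone and GC-corrected (-0.32 and -0.29; with both, -0.26 and not past the threshold). HSPH1, CHORDC1 and HSPB1 stood at 0.09, 0.08 and -0.19 for replicate 1 alone and at 0.10, 0.04 and 0.004 GC-corrected (limma, BH adjusted p from 0.167 to 0.982). HSPA1B is uncertain because HSPA1A is nearly identical. Of 27 NRF2 genes 1 rose and 2 fell (1 and 1 by edgeR), or 1 and 4 adjusted over the list alone (median -0.05, camera adjusted p = 0.397), NQO1, a quinone reductase gene, at -0.23 (SE 0.061) and the ferritin gene FTL at -0.35 (SE 0.105). Neither passed for replicate 1 alone (-0.16 and -0.01), nor FTL GC-corrected (-0.23).

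Of 22 fatty acid synthesis genes 3 rose and 0 fell by limma (5 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by edgeR), or 4 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.609). SCD, the stearoyl-CoA desaturase gene, rose by 0.24 (SE 0.057), ACSL4, an acyl-CoA synthetase gene, by 0.52 (SE 0.072), and PLIN2, a lipid droplet gene, by 0.33 (SE 0.093; 0.25 and not past the threshold for replicate 1 alone). Of 17 fatty acid oxidation and PPAR genes 2 rose and 2 fell (1 and 1 by DESeq2), or 2 and 3 adjusted over the list alone (median -0.10, camera adjusted p = 0.249), ANGPTL4 and PLIN2 higher and the carnitine palmitoyltransferase gene CPT2 and the thiolase gene ACAA1 lower at -0.71 (SE 0.139) and -0.35 (SE 0.103). CPT2 and ACAA1 did not pass for replicate 1 alone (-0.41 and -0.41), nor ACAA1 GC-corrected (-0.33). Of 13 xenobiotic metabolism genes 2 rose and 2 fell, also when adjusted over the list alone (median -0.14, camera adjusted p = 0.459). The aryl hydrocarbon receptor gene AHR and TIPARP rose by 0.41 (SE 0.110) and 0.39 (SE 0.071), while AHRR, the receptor's repressor, and SULT1A1, a sulfotransferase gene, fell by 0.40 (SE 0.068) and 0.44 (SE 0.091). AHR and SULT1A1 did not pass for replicate 1 alone (0.32 and -0.32), nor AHR GC-corrected (0.22).

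Transcripts of secreted hepatocyte proteins were scarce in both groups. Of 27 such genes fixed in advance 18 were in the deposited table, which holds no gene at 0 in all libraries. ALB, TTR, APOA2, APOB, APOC3, APOH, ITIH1, HP and PLG were absent from it, for a reason that was not tested. Of the 18, 4 had a mean of at least 10 normalised counts. The highest, the retinol-binding protein gene RBP4, stood at 89.9 ± 6.0 in Flag and 88.6 ± 4.4 in Flag-PPFIA1 (SD, n = 3). APOA1, an apolipoprotein gene, stood at 1.1 ± 1.2 in Flag and was listed at 0 in all 3 Flag-PPFIA1 libraries. All 18 together took 0.00152% of normalised counts. The liver transcription factor gene HNF4A stood at 51.6 ± 17.2 and 65.8 ± 5.6. Genes of fetal and progenitor liver spanned low and high levels. Of 15 fixed in advance 12 were in the deposited table, and AFP, GPC3 and IGF2 were absent from it. Of the 12, 7 had a mean of at least 10 normalised counts, and KRT19 and LIN28B had means of 0.6 and 0.5 over all libraries. The higher ones included IGF2BP3 at 1239.2 ± 10.3 and 1356.8 ± 19.7, CD24 at 815.4 ± 54.9 and 817.5 ± 57.2, and SOX9, which rose from 169.8 ± 42.6 to 275.2 ± 17.4 (log2 0.73, SE 0.161, limma, BH adjusted p = 0.0166). HepG2 is known as a line that makes secreted hepatocyte proteins, so levels this low are at odds with the label. The identity of the line was not tested here, the name HepG2 is used as the labels give it, and the genes named here were picked from the fixed lists after their values were seen.

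The remaining lists are given as counts of genes that rose and fell over all genes by limma. None of the 4 tested secreted hepatocyte genes and none of the 4 bile acid genes was called (0 and 0, also by DESeq2 and edgeR; 1 of each lower at an unadjusted p under 0.05), and adjusted over the list alone 1 secreted gene fell. Of 9 hepatocyte transcription factor genes 1 rose (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.712), of 7 fetal liver genes 1 rose (1 and 0; 0.385), of 13 gluconeogenesis and insulin genes 1 rose (0 and 0; 0.3), and of 12 nucleic acid sensing genes 1 rose (1 and 0; 0.151). Of 13 Wnt targets 0 changed, also at an unadjusted p under 0.05 and by DESeq2 and edgeR (0 and 0; 0.609). Of 10 Notch targets 1 rose and 1 fell, the latter by neither DESeq2 nor edgeR (4 and 2; 0.761), of 27 MYC and ribosome biogenesis genes 2 fell, 1 by DESeq2 (0 and 0; 0.813), of 32 autophagy and lysosome genes 2 fell (0 and 2; 0.631), and of 25 presynaptic and vesicle genes 1 rose (1 and 0; 0.860). Among markers of other cell types, 1 of 10 fibroblast genes rose, 0 by DESeq2, and 1 fell (1 and 1; 0.756), 1 of 3 endothelial genes fell (0 and 1), 0 of 2 immune genes changed, also at an unadjusted p under 0.05 and by DESeq2 and edgeR (0 and 0), and 1 of 5 kidney and embryonic line genes fell, 0 by DESeq2 (0 and 1; 0.397). RGS5 takes 2 of the 10 fibroblast entries, under separate identifiers that differ in direction. One stood at 12.2 ± 1.1 normalised counts in Flag and 26.9 ± 5.6 in Flag-PPFIA1, the other at 25.3 ± 8.3 and 23.0 ± 6.1 (SD, n = 3). The most abundant genes of the fibroblast, endothelial, and kidney and embryonic line lists over all 6 libraries were COL1A1 at 571.3, ESAM at 1669.2 and TLE4 at 578.4 normalised counts. The Notch and fibroblast medians (-0.03 and -0.07) had the opposite sign to their means (0.03 and 0.01), and the test direction was up for Notch and down for fibroblast genes. The gluconeogenesis list had a median of 0.08 over all libraries and 0.19 for replicate 1 alone. In the latter fit, which rests on 1 Flag-PPFIA1 library, it passed by camera at the preset correlation. GC-corrected, the 2 autophagy and lysosome genes that fell did not pass, and 2 others did, ULK1 higher at 0.28 and GABARAPL2 lower at -0.30 (limma, BH adjusted p = 0.00927 and 0.0368).

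The authors' deposited table holds 1510 genes with an adjusted p under 0.05, 874 higher and 636 lower in Flag-PPFIA1 cells, of which 10 have an absolute log2 fold change of at least 1. DESeq2 on the recovered reads called the same 1510 genes in the same directions, so its counts are not a separate result. Of these calls in the authors' deposited table, 1393 were also called by limma, all 1393 in the same direction, 117 were not, and limma called 290 further genes. Log2 fold changes of the authors' deposited table and of the limma fit had a Spearman correlation of 0.994 across genes, which are not independent replicates. In the authors' deposited table PPFIA1 has a log2 fold change of 0.95 (adjusted p = 1.18e-26) and SMN1 of 2.01 (adjusted p = 1.01e-53). The count of shared calls was 183, 62 and 224 without Flag replicates 1, 2 and 3 and 276 and 146 without Flag-PPFIA1 replicates 2 and 3, and 180 for replicate 1 alone and 481 GC-corrected.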

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

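The GC correction, the term for Flag-PPFIA1 replicates 2 and 3 and both together were chosen after seeing the data; the other alternatives were fixed beforehand. PPFIA1 stayed higher and past the threshold in every limma, edgeR and DESeq2 setting (log2 from 0.813 to 1.01) except limma without the intensity trend, where the value of 0.944 had a limma BH adjusted p of 0.0933. In that setting 0 genes, 0 at 2-fold and 0 shared with the authors' deposited calls passed by limma, against 3483 at an unadjusted p under 0.05, 1510 by DESeq2 and 1572 by edgeR; it uses 1 common prior spread in place of one that follows intensity. The count of changed genes, 1683, became 733 GC-corrected, 209 with the term, 241 with both and 165 at an adjusted p under 0.01, and stayed between 1505 and 1888 in the other settings that kept all libraries. Without 1 library it ranged from 64 (without Flag replicate 2) to 4809 (without Flag-PPFIA1 replicate 1). The 2-fold count, 53, became 85 with no filter, 21 at a minimum mean of 50 (by construction, since fewer genes of low counts are tested), 26 with pseudocount 10 (which shrinks their fold changes), 10 with DESeq2, 32 GC-corrected, 13 with the term, 16 with both, and 5 to 243 without 1 library. Calls shared with the authors' deposited table, 1393, became 481 GC-corrected, 180 with the term, 165 with both, and 62 to 1510 without 1 library. Camera passed 10 lists, 0 with an estimated correlation, and 9 to 14 in the other settings. Fry called 14 lists, 8 of the 10 and 6 others, and did not call the ribosomal and oxidative phosphorylation lists (fry adjusted p = 0.0839 and 0.0521). For these counts the cause was not tested beyond what is stated.

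Several lists changed their camera direction, which is set by the test statistics of a list relative to other genes and need not match the sign of its median, and none of them passed in the setting named; medians are given. The extracellular matrix list, whose camera direction was down, turned up, with a median of 0.009 with no filter, 0.032 GC-corrected, 0.016 with the term and 0.053 with both, and medians from -0.012 to 0.027 without 1 library. The xenobiotic list turned to 0.101 at a minimum mean of 50. GC-corrected, the interferon list (0.034) and mitochondrial mRNAs (-0.023) turned down. With the term, heat shock genes turned down (-0.018, against -0.002) and YAP/TAZ targets and metallothioneins up (0.051 and 0.089), and with both the medians were -0.04, 0.031 and 0.04, with NRF2 genes turned up (0.015). Without Flag-PPFIA1 replicate 1 the epithelial-mesenchymal list turned down (-0.043; -0.043 to 0.094 without 1 library), as did mitochondrial mRNAs, whose median stayed positive (0.016; 0.016 to 0.065). Without Flag-PPFIA1 replicate 2 heat shock genes turned down (-0.014; -0.014 to 0.058). Named genes whose fold change turned were HSPB1 (0.004, GC-corrected), MT-ND4L and MT2A (0.133 and 0.03 with the term; 0.097 and 0.077 with both) and, with both, SREBF1 (0.028), FTL (0.045), CHORDC1 (-0.065) and MT-ND6 (-0.016). The cause was not tested.

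Of 116 called genes among the 124 named besides PPFIA1, calls were lost in 35 GC-corrected, 72 with the term, 73 with both, 116 without the intensity trend, 13 with DESeq2, 17 with edgeR, 66, 92 and 63 without Flag replicates 1, 2 and 3, and 58 and 73 without Flag-PPFIA1 replicates 2 and 3; without Flag-PPFIA1 replicate 1 none of those tested was lost and 5 were gained. With the replicate block 1505 genes (1380 shared with the 1683), 66 at 2-fold, 1251 shared with the authors' deposited table and 10 lists passed, PPFIA1 stood at 0.944, and 4 named genes were lost and 1 gained. Libraries with equal numbers had correlations of deviations of -0.079, -0.152 and 0.067, which show no pairing by number. With 3 libraries per group, and Flag-PPFIA1 replicate 1 far from replicates 2 and 3, these values cannot exclude a shared day. Depth limits genes near 10 normalised counts, for which a few reads change the fold change.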

Other observations

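All tests of explanations given here were chosen after the pattern they address was seen. Only the test of the genes around SMN1 was written before its own outcome was seen, and it too followed the finding that SMN1 rose. Outside the fixed lists, genes with varied roles rose in the Flag-PPFIA1 libraries; these examples were chosen after their values were seen. By limma 122 genes, 107 higher and 15 lower, were called with 1 direction in all 4 fits, namely uncorrected and GC-corrected, each with and without the term for Flag-PPFIA1 replicates 2 and 3, and 71 of them are in no fixed list. The 71 include PPFIA1 itself, which is in the liprin list but was left out of every list test. BHLHE40, a transcriptional repressor of the circadian clock that is also induced by low oxygen, rose from 1982 ± 105.0 to 3404 ± 320.0 normalised counts (SD, n = 3; log2 0.78, SE 0.074), and PTGS2, the inducible cyclooxygenase gene, from 364.7 ± 9.53 to 654.7 ± 16.8 (log2 0.84). ERRFI1, a feedback inhibitor of the EGF receptor, rose by log2 0.76 (SE 0.079), PRDM1, a transcriptional repressor, by 0.73 (SE 0.108), and the protease inhibitor gene SERPINE2 by 0.74 (SE 0.094). The chemokine receptor gene CXCR4 rose from 577.5 ± 38.5 to 902.8 ± 37.7 (log2 0.65). IGFBP3, which encodes a binding protein of insulin-like growth factors, rose by 0.61 (SE 0.099). VHL, the ubiquitin ligase subunit that recognises hydroxylated HIF, rose by 0.44 (SE 0.072), the fucosyltransferase gene FUT11 by 0.53 (SE 0.096) and the adenylate kinase gene AK4 by 0.39 (SE 0.077).

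The keratin gene KRT17 rose from 3459 ± 237.0 to 4927 ± 226.0 normalised counts (SD, n = 3; log2 0.51). MCL1, an antiapoptotic BCL2 family gene, rose by log2 0.46 (SE 0.062), NAMPT, of NAD synthesis, by 0.51 (SE 0.070), and the long noncoding RNA LUCAT1 by 0.54 (SE 0.088). Among the 15 that were lower in all 4 fits, the transporter gene ABCA13 fell from 326.6 ± 28.9 to 193.6 ± 8.68 (log2 -0.75), SCARA3, a scavenger receptor gene, fell by 0.52 (SE 0.086) and CELSR2, an adhesion-type cadherin gene, by 0.44 on the log2 scale (SE 0.071). The snoRNA host gene SNHG3 fell by 0.35 (SE 0.067).

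Hypoxia genes were raised in each Flag-PPFIA1 library. If the libraries that stand apart, replicates 2 and 3, carried the rise, their members would exceed replicate 1 by a median log2 of 0.742, whereas they differed by 0.001 (SD 0.165 over 25 members), which argues against it. A GC content trend as the whole cause is argued against too, since the GC-corrected median was 0.439 (SD 0.247; uncorrected 0.494) and the list passed (camera adjusted p = 2.87e-19), although with an estimated correlation the uncorrected list did not (adjusted p = 0.210). Culture conditions that differed between the groups rather than PPFIA1, such as cell density, could give the same rise: 0 of 10 culture and extraction labels differed. The groups are different cells by design, so this cannot be told apart from an effect of PPFIA1.

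SMN1 rose more than PPFIA1 itself. Reads that moved between SMN1 and its near-identical copy SMN2 would leave their sum level, but the sum rose from 377.6 ± 38.6 to 1067.2 ± 24.9 normalised counts (SD, n = 3; log2 ratio 1.499). A change of the whole 5q13 segment was taken to raise its neighbours by a log2 of at least 1.013, a cut-off chosen from the SMN1 change. The 6 tested genes within 1 Mb had a median of 0.01 (SD 0.215). Among them SERF1B, GTF2H2B and AC140134.1 had SEs of 0.619, 0.438 and 0.389, so they say little. The better measured ones lay below the cut-off. BDP1 rose by 0.38 (SE 0.109, limma, BH adjusted p = 0.0392), GTF2H2 stood at 0.38 (SE 0.134, limma, BH adjusted p = 0.0794) and MCCC2 at -0.07 (SE 0.073). An effect of PPFIA1, a smaller change of copy number and a difference between the cells that received each construct may each give this value and were not tested apart.

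Ribosomal protein and oxidative phosphorylation mRNAs had a median log2 change of -0.12 over 72 genes, of which 13 of 41 and 11 of 31 fell by limma (5 and 8 by edgeR, 0 and 0 for replicate 1 alone by limma, 12 and 9 at an unadjusted p under 0.05). Both lists passed by camera but not with an estimated correlation (adjusted p = 0.571 and 0.463) or by fry (0.0839 and 0.0521). The GC-corrected median was -0.11 (SD 0.247) and both lists passed (highest camera adjusted p = 0.00356), which argues against a GC content trend as the whole cause. The trend with gene length between the libraries was not corrected for, so its part in the fall was not tested. Flag-PPFIA1 replicates 2 and 3, which stand apart, differed from replicate 1 by -0.056 (SD 0.331), where -0.179 would be needed for them to carry the shift. For replicate 1 alone the medians were -0.077 for ribosomal protein and -0.082 for oxidative phosphorylation genes, against -0.096 and -0.158 over all libraries. Those values rest on 1 library. With the spread over members, a shift carried by replicates 2 and 3 stays open and cannot be told apart from an effect of PPFIA1.

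The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. By limma the real split gave 1683 changed genes against at most 0 in another, 53 at 2-fold against at most 0, and 10 lists against at most 4; 1 of the 10 splits, the real one, reached each value.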
